A study of Mus musculus with 12 samples.

How the data were processed

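RNA was sequenced from 12 libraries of cortex and hippocampus of C57/Bl6 mice at postnatal day 21 that carried a green fluorescent tag on the ribosomal protein Rpl10a under the Aldh1l1 promoter, which is active in astrocytes. Translating ribosome affinity purification (TRAP) pulls such tagged ribosomes, and the RNA bound to them, out of a lysate with antibodies against the tag. The libraries form 4 groups of 3: input to the whole-tissue purification (cortex input), its immunoprecipitate (cortex TRAP), input from a synaptoneurosome layer (a sucrose-gradient fraction that holds pinched-off synapses and the processes around them), and the immunoprecipitate of that layer (PAP TRAP, for peripheral astrocyte process TRAP). Groups were taken from the sample labels. The labels give all samples the same extract protocol, so details of how the cortex samples differed in handling rest on the source names alone.

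Per the labels' protocols, samples were treated with cycloheximide, which stops ribosomes on their messages, at 1 ug/mL and with TTX, a sodium channel blocker, at 1 mM. cDNA was made from 2 ng of RNA and amplified by SPIA, a linear isothermal method, and 500 ng of cDNA in fragments of about 200 bp entered library preparation. The deposited values are whole-number counts of reads per gene that the authors had not normalized, judged from the files, which also hold HTSeq's rows for reads assigned to no gene. Per the submitters' processing notes, Trimmomatic 0.32, Bowtie2, STAR and HTSeq were used, with no role or order stated. The genome build, annotation and strand setting are not given in the sources used here, so counts of antisense and overlapping genes, and of genes with near-identical copies such as ribosomal proteins, are uncertain. SPIA amplification without molecular identifiers means that counts are not independent molecules, and zero-count floors of 3 counts cover counting error only. The intervals of fold changes come from the SE of the fit, so they also hold the spread between libraries.

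The files list 41388 gene identifiers, of which 40340 were given a symbol through a table of identifiers. Positions, transcript lengths and GC content came from GENCODE M21 (GRCm38), matched by identifier. Rows naming no gene held 20.3% to 55.5% of all counts per library and stayed out of library sizes and tests. Gene counts per library ranged from 4918110 to 17554000. The 37 genes of the mitochondrial chromosome stayed in the library sizes, and TMM factors ranged from 0.191 to 2.46.

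Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15), which left 13364. All 12 libraries were fitted together with 1 mean per group by the edgeR quasi-likelihood method (edgeR 4.0.16, R 4.3.3) with TMM scaling. The 5 comparisons were cortex TRAP against cortex input, PAP TRAP against synaptoneurosome input, PAP TRAP against cortex TRAP, synaptoneurosome input against cortex input, and the difference between both enrichments over input (an interaction term). Adjusted p-values are Benjamini-Hochberg values over all genes tested from this edgeR quasi-likelihood F test, called at 0.05. Fold changes are log2 values ± SE with 3 libraries per group. Levels are normalized CPM with SD. A fitted change against a group near 0 counts depends on the prior count and is no bound on the true fold.

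In all, 25 gene lists of cell types, synaptic and metabolic groups and organelles were fixed before the data were examined, as were the tests, the groups and the rule for named genes. Lists with at least 5 genes tested (24 lists) were tested by camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated one, Benjamini-Hochberg adjusted over the 120 pairs of list and comparison. Named genes were, per comparison and intersection, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 3 and, for comparisons between groups, no overlap between groups. For each list described, up to 2 members that rose and 2 that fell, by smallest p, were named, together with a fixed set of astrocyte, neuronal, glial, nuclear and mitochondrial genes. Genes named outside this rule are said to be so, and some genes that the rule names are not reported here. Sets of genes called in a pair of comparisons that share libraries were set beside simulations of unchanged groups.

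Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit of the compared groups alone, the replicate number as a block, a minimum fold of 1.5 (glmTreat), fry (limma's directional test) in place of camera, and each library left out in turn. Others were added after the data had been seen: no mitochondrial genes, nuclear counts thinned to the smallest library, offsets corrected for GC content or transcript length (loess span 0.3, 99.4% of genes with a value), and list tests without cortex TRAP replicate 1 or PAP TRAP replicate 2. In data simulated from these libraries for PAP TRAP against synaptoneurosome input, with 50 genes changed at each size, the test called 0% of genes changed 1.5-fold, 2% of those changed 2-fold, 38% at 4-fold and 60% at 8-fold, with 1 false call among 13364 genes. For the difference between enrichments it called 0% at 2-fold, 12% at 4-fold and 32% at 8-fold. Cldn5, an endothelial gene, failed the filter (7 counts in cortex TRAP replicate 1 and 0 in the others) and was not tested.

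Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Counts of replicate pairs differed with a chi-square per degree of freedom of 8.38 to 85.2, above what sampling of reads alone gives. No library was therefore treated as a copy of another. Separate amplifications of the same RNA are not excluded by this, since amplified counts are not independent molecules. An immunoprecipitation from mice without the tag was not analysed here, so no control gives a level for binding of untagged RNA to the beads. Transcripts of the mitochondrial chromosome took 1.13% of the counts in cortex TRAP and 40.9% in PAP TRAP. Whether they came in by such binding was not tested.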

Results

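The 12 libraries cover 4 groups of 3 libraries each: cortex input, cortex TRAP, synaptoneurosome input and PAP TRAP. The design compares messages on astrocyte ribosomes of the whole tissue with those on astrocyte ribosomes of a fraction that holds synapses and the fine processes around them, away from the cell body. Transcripts of the mitochondrial chromosome took 48.3% ± 3.01 (SD, n = 3) of the counts in cortex input, 1.13% ± 0.135 in cortex TRAP, 88.5% ± 4.2 in synaptoneurosome input and 40.9% ± 6.08 in PAP TRAP. Nuclear genes were left with 5844710 ± 568275 counts in cortex input, 6520100 ± 1496650 in cortex TRAP, 1776550 ± 605818 in synaptoneurosome input and 6128930 ± 604929 in PAP TRAP. The synaptoneurosome inputs are the shallowest libraries for nuclear genes. The Spearman correlation across genes between PAP TRAP and synaptoneurosome input libraries lay between 0.834 and 0.884, and that between PAP TRAP and cortex TRAP libraries between 0.657 and 0.767. Between PAP TRAP and cortex input libraries it lay between 0.815 and 0.866. PAP TRAP replicate 2 had the highest correlations with the cortex TRAP libraries, 0.743 to 0.767, against 0.657 to 0.697 for the other PAP TRAP libraries.

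**Figure D1:**
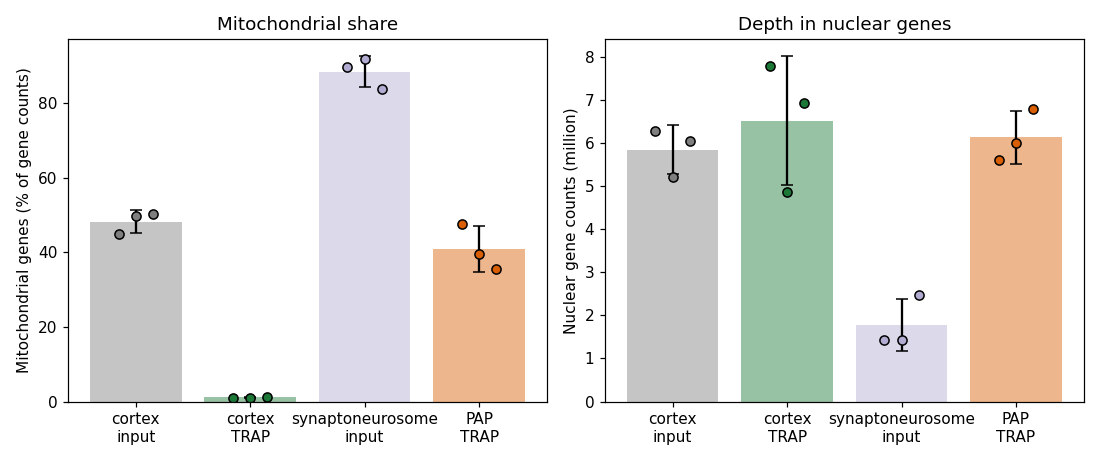
Share of gene counts on the mitochondrial chromosome (percent) and counts on nuclear genes (scaled as the axis states) per group, with bars for means, error bars for SD and points for the 3 libraries of each group. Mitochondrial transcripts ranged from 1.13% in cortex TRAP to 88.5% in synaptoneurosome input, where nuclear genes kept 1776550 counts.

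Cortex TRAP against cortex input asks which messages the tagged ribosomes of the whole tissue carry. Astrocyte genes were far above their input. Glul, which makes glutamine from glutamate, was 21.4-fold higher (95% interval 14.1 to 32.3), with 6038 ± 910 normalized CPM in cortex TRAP against 282 ± 37.3 in cortex input (SD, n = 3). Gfap, the intermediate filament of astrocytes, was higher by 4.49 ± 0.34 on the log2 scale, Slc1a3, a glutamate transporter, by 4.11 ± 0.27, Slc1a2, the main glutamate transporter of the forebrain, by 3.28 ± 0.27, Aqp4, a water channel, by 3.84 ± 0.37, and Gja1, a gap junction protein, by 3.51 ± 0.37. Aldh1l1, whose promoter drives the tag, rose by 3.46 ± 0.46 (adjusted p = 7.06e-06). Neuronal and myelin genes were far below input: Slc17a7, which loads glutamate into synaptic vesicles, at -3.56 ± 0.28, Gad1, which makes GABA, at -3.17 ± 0.34, and Mbp, a myelin protein, at -2.63 ± 0.31 (-3.26 without cortex TRAP replicate 2).

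By list, 29 of 29 astrocyte markers rose in cortex TRAP (29 adjusted over the list alone, median log2 change 4.19, camera adjusted p = 9.02e-44). Of 22 neuron markers, 21 fell (21 adjusted over the list alone, median -3.17, adjusted p = 6.62e-23). Of 17 dendritic and neuropil mRNAs, messages described in dendrites, 16 fell (16 adjusted over the list alone, median -1.87, adjusted p = 9.5e-10), and 17 of 18 genes of presynaptic vesicles and release fell (18 adjusted over the list alone, adjusted p = 5.03e-19), among them Pclo (-4.25 ± 0.28) and Bsn (-3.30 ± 0.25), scaffolds of the release site. Myelinating oligodendrocyte markers fell in 12 of 16 members (12 adjusted over the list alone, adjusted p = 7.78e-07). Microglia markers fell in 9 of 18 (10 adjusted over the list alone, adjusted p = 0.00128, and adjusted p = 0.219 with an estimated correlation), led by Csf1r, a growth factor receptor of microglia, at -3.38 ± 0.39. All 11 mitochondrially encoded mRNAs tested fell (median -5.94, 11 adjusted over the list alone, adjusted p = 8.5e-19), and 5 of 7 nuclear long noncoding RNAs fell (6 adjusted over the list alone, adjusted p = 1.32e-05, and adjusted p = 0.0897 with an estimated correlation), including Malat1, which stays in the nucleus, at -5.53 ± 0.52. Ependymal and choroid plexus markers held 0.00828% of the nuclear counts in cortex input and 0.0639% in cortex TRAP. As a list they were not called (2 of 5 higher, 2 adjusted over the list alone, adjusted p = 0.179), but Ttr, a carrier of thyroid hormone, rose by 3.41 ± 0.57. Rarres2, a secreted chemoattractant, had 4.84 ± 1.58, and 6.92 without cortex input replicate 1. Its call ended without cortex input replicates 2 or 3 or cortex TRAP replicates 1 or 3 (adjusted p from 0.0585 to 0.117).

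Groups with known astrocyte functions rose as well. Glutamate and GABA uptake and metabolism had 11 members higher and 2 lower of 13 (11 and 2 adjusted over the list alone, adjusted p = 7.71e-11). The lower ones were the aminotransferases Got1 (-2.53 ± 0.32) and Got2 (-1.84 ± 0.43). Water, potassium and gap junction channels had 10 higher and 1 lower of 11 (10 and 1 adjusted over the list alone, adjusted p = 2.34e-12), the lower one being the chloride transporter Slc12a2 (-2.04 ± 0.35). Astrocyte synaptic regulators, secreted or surface proteins that act on synapses, rose in 14 of 18 members (14 higher and 1 lower adjusted over the list alone, adjusted p = 3.22e-11), with Sparc at 4.26 ± 0.31 and its relative Sparcl1 at 3.49 ± 0.25. Nuclear-encoded respiratory chain genes rose in 37 of 59 (43 adjusted over the list alone, adjusted p = 9.97e-09, and adjusted p = 0.178 with an estimated correlation), and cytosolic ribosomal protein genes in 28 of 72 (31 adjusted over the list alone, adjusted p = 4.62e-06, and adjusted p = 0.204 with an estimated correlation).

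In total 4737 of 13364 genes were called, 2127 higher and 2610 lower (edgeR quasi-likelihood, BH). Among the large rises were Ttpa, which carries vitamin E (6.01 ± 0.66, and 5.30 without cortex TRAP replicate 1), and Acsbg1, an acyl-CoA synthetase (5.92 ± 0.39). The estimated rise of Dnm2, a membrane-fission GTPase, of 6.81 ± 1.33 became 1.16 without cortex TRAP replicate 1 (adjusted p = 0.0593), and that of Atp13a4, a transport ATPase, went from 6.32 ± 1.24 to 2.48 (adjusted p = 0.0741).

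Synaptoneurosome input against cortex input shows what the fractionation did to total RNA before any immunoprecipitation. Astrocyte and microglial transcripts and mitochondrially encoded mRNAs made up more of the fraction, and nuclear long noncoding RNAs less. Slc1a2 was 7.56-fold higher (95% interval 5.17 to 11), rising from 2358 ± 255 to 17830 ± 565 normalized CPM (SD, n = 3). Sparc rose by 3.13 ± 0.30, Sparcl1 by 2.89 ± 0.24 and Kcnj10, a potassium channel of astrocytes, by 2.66 ± 0.31. Itgam, an integrin of microglia, rose by 3.79 ± 0.59 and Ctss, a lysosomal protease, by 3.28 ± 0.43, while Malat1 fell by 4.21 on the log2 scale (SE 0.49), and by 5.09 without synaptoneurosome input replicate 3.

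Of 29 astrocyte markers, 20 rose and 0 fell in the fraction (23 and 0 adjusted over the list alone, median 1.60, adjusted p = 1.15e-25). Astrocyte synaptic regulators rose in 11 of 18 (13 adjusted over the list alone, median 1.96, adjusted p = 1.14e-18), and water, potassium and gap junction channels in 8 of 11 (9 adjusted over the list alone, adjusted p = 3.54e-15). Microglia markers rose in 10 of 18 (14 adjusted over the list alone, median 2.57, adjusted p = 1.83e-12). All 11 mitochondrially encoded mRNAs rose (11 adjusted over the list alone, median 3.85, adjusted p = 7.44e-36), while respiratory chain genes encoded in the nucleus had 2 of 59 higher (2 adjusted over the list alone, median 0.13, adjusted p = 0.317). Genes of ER translocation and chaperones, which fold secreted and membrane proteins, rose in 11 of 22 (15 adjusted over the list alone, median 1.32, adjusted p = 1.55e-11), with the chaperones Canx at 1.84 ± 0.23 and Hspa5 at 1.64 ± 0.28. Neuronal lists were mixed. Dendritic and neuropil mRNAs rose in 9 of 17 (9 adjusted over the list alone, median 0.98, adjusted p = 3.25e-06, and adjusted p = 0.0572 with an estimated correlation), with the postsynaptic scaffold Shank1 at 2.04 ± 0.30 and the axonal motor Kif1a at 2.03 ± 0.22. Neuron markers had 5 higher and 3 lower of 22 (7 and 3 adjusted over the list alone, adjusted p = 0.401). Of 7 nuclear long noncoding RNAs, 3 fell (4 adjusted over the list alone, adjusted p = 3.93e-09).

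The comparison called 1246 genes, 970 higher and 276 lower (3280 at an unadjusted p under 0.05). This count moved by over 1.5 times when a library was left out: 608, 648 and 613 genes without cortex input replicates 1, 2 and 3, and 814 without synaptoneurosome input replicate 1. The 276 lower genes became 83, 88 and 61 without cortex input replicates 1, 2 and 3, and 108 and 117 without synaptoneurosome input replicates 1 and 2. DESeq2 called 2035 genes and a fit of these groups alone 2251.

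PAP TRAP against synaptoneurosome input asks which messages the immunoprecipitation raised within the fraction. Part of the astrocyte markers (11 of 29) and of the dendritic messages (9 of 17) rose, as did Mbp. Glul was 2.77-fold higher (95% interval 1.92 to 4.0, adjusted p = 0.00293), at 2518 ± 929 against 908 ± 71.6 normalized CPM (SD, n = 3). Aldoc, a glycolytic enzyme of astrocytes, rose by 1.56 ± 0.26, Scd1, a fatty acid desaturase, by 1.44 ± 0.25, and Fasn, the fatty acid synthase, by 1.42 ± 0.26. Camk2a, a kinase whose message is carried into dendrites, was 3.25-fold higher (2.03 to 5.20, adjusted p = 0.00615), at 9995 ± 2179 against 3075 ± 306 normalized CPM, and Mbp, whose message is carried into myelin, 3.36-fold (2.17 to 5.20). Snap25, a release protein of neurons, fell by 1.42 on the log2 scale (SE 0.27), and Syt1, the calcium sensor of release, by 1.12 (SE 0.23).

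Astrocyte markers rose in 11 of 29 members and fell in 0 (20 and 0 adjusted over the list alone, median 1.09, adjusted p = 2.1e-14, and adjusted p = 0.0884 with an estimated correlation). They held 5.20%, 10.1% and 6.73% of the nuclear counts in PAP TRAP replicates 1, 2 and 3, against 4.30% to 5.18% in the synaptoneurosome inputs, and without PAP TRAP replicate 2 the list had adjusted p = 3.36e-09. Dendritic and neuropil mRNAs rose in 9 of 17 (12 higher and 1 lower adjusted over the list alone, median 1.16, adjusted p = 1.37e-09), with the postsynaptic scaffolds Dlgap3 at 2.32 ± 0.31 and Shank3 at 2.25 ± 0.31. With offsets corrected for GC content these became 1.53 and 1.52. Neuron markers had 1 higher and 4 lower of 22 (1 and 7 adjusted over the list alone, median -0.38, adjusted p = 0.000123, and adjusted p = 0.253 with an estimated correlation). Microglia markers fell in 4 of 18 (11 adjusted over the list alone, median -1.83, adjusted p = 1.69e-10), with Ctss at -1.91 ± 0.40. Mitochondrially encoded mRNAs fell in 8 of 11 (11 adjusted over the list alone, median -2.58, adjusted p = 3.56e-22), with mt-Co1, a subunit of the last respiratory complex, at -1.38 ± 0.23. Glutamate and GABA uptake and metabolism rose in 2 of 13 (8 adjusted over the list alone, adjusted p = 0.000163, and adjusted p = 0.116 with an estimated correlation). These genes held 4.81%, 9.36% and 6.28% of the nuclear counts in PAP TRAP replicates 1, 2 and 3, against 4.06% to 4.89% in the synaptoneurosome inputs. Without PAP TRAP replicate 2 the list had adjusted p = 0.00171.

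Among the largest changes, Itpkb, an inositol phosphate kinase, rose by 3.53 ± 0.46 and Lcp1, an actin-bundling protein of blood lineages, by 3.48 ± 0.64. Igf2, a growth factor, fell by 3.87 on the log2 scale (SE 0.36), from 71.0 ± 20.2 to 4.87 ± 1.56 normalized CPM. Irf4 and Pou2af1, transcription factors of B lineage cells, were also called. Pou2af1 had 0 counts in all 3 synaptoneurosome inputs and 74, 788 and 108 in the PAP TRAP libraries. Without PAP TRAP replicate 2 the adjusted p was 0.0542 for Pou2af1 and 0.148 for Irf4. Without synaptoneurosome input replicates 1 or 3 it was 0.0512 and 0.0606 for Pou2af1, and without PAP TRAP replicate 1 or synaptoneurosome input replicates 1, 2 or 3 it lay between 0.0509 and 0.167 for Irf4, which had 0.0582 with GC-corrected offsets.

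Several astrocyte genes did not pass this test: Slc1a2 (0.72 ± 0.24, adjusted p = 0.102), Slc1a3 (0.72 ± 0.24, adjusted p = 0.0949), Kcnj10 (0.92 ± 0.29, adjusted p = 0.0736), Aldh1l1 (1.44 ± 0.44, adjusted p = 0.0685), Aqp4 (0.38 ± 0.33) and Gja1 (0.38 ± 0.34). With mitochondrial genes left out of the fit Slc1a2, Slc1a3, Kcnj10 and Aldh1l1 did pass (adjusted p from 0.0252 to 0.0466). Aqp4 and Gja1 turned to -0.17 and -0.13 without PAP TRAP replicate 2. Gfap was called at 1.37 ± 0.30 but had an adjusted p of 0.0530 without synaptoneurosome input replicate 3 and 0.0633 with GC-corrected offsets. Sparc (1.11 ± 0.28) lost its call without any of synaptoneurosome input replicates 1, 2 and 3 or PAP TRAP replicate 2 (adjusted p from 0.0602 to 0.139), and had 0.0774 with GC-corrected offsets. In total 605 genes were called, 401 higher and 204 lower, with 2686 at an unadjusted p under 0.05. The count was 308, 304 and 292 without synaptoneurosome input replicates 1, 2 and 3, 329 and 363 without PAP TRAP replicates 2 and 3, 329 with GC-corrected offsets and 1253 with DESeq2. The 204 lower genes became 86 without PAP TRAP replicate 2 and 567 with DESeq2. The 401 higher genes became 193 without synaptoneurosome input replicate 3 and 686 with DESeq2.

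**Figure D2:**
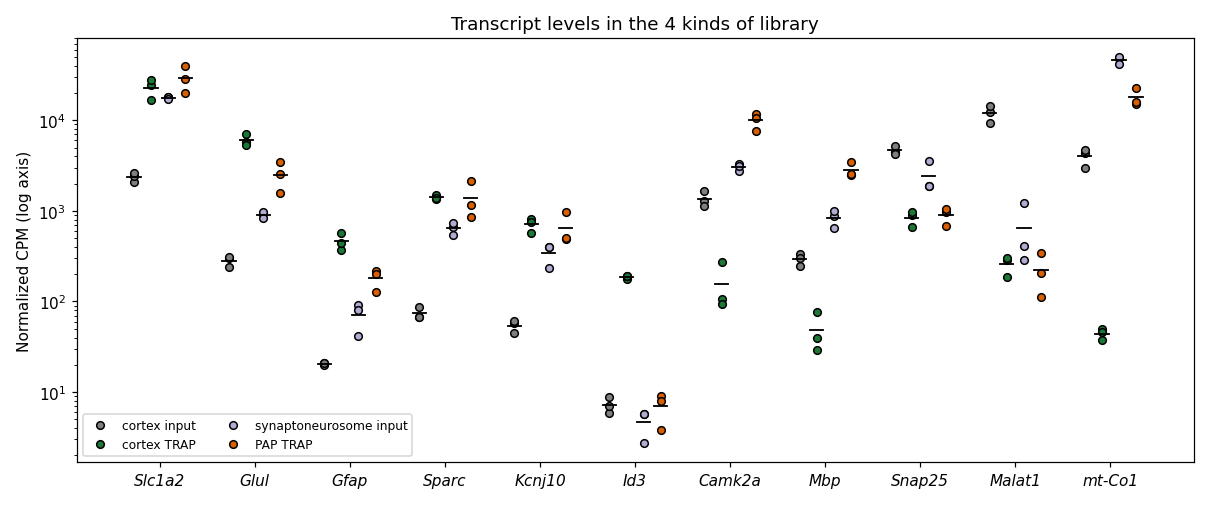
Normalized CPM on a log axis for 11 genes in the 4 groups, with points for the 3 libraries of each group and a bar at their mean. Glul stood at 282 in cortex input, 6038 in cortex TRAP, 908 in synaptoneurosome input and 2518 in PAP TRAP, while Camk2a was lowest in cortex TRAP (158) and highest in PAP TRAP (9995).

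PAP TRAP against cortex TRAP compares both immunoprecipitates, which is the main question of the series. The lists of dendritic, presynaptic and myelin messages and of mitochondrially encoded mRNAs were higher in PAP TRAP. Not all of them stood above their own input. Presynaptic genes held 1.51% of the nuclear counts in PAP TRAP against 2.33% in synaptoneurosome input. Neuron markers held 0.973% against 1.72% and microglia markers 0.0396% against 0.128%. Dendritic messages (3.80% against 1.97%) and myelin markers (0.980% against 0.796%) went the other way. Of 29 astrocyte markers 24 were lower, though the call of their list was lost with an estimated correlation. Camk2a was 63.4-fold higher (95% interval 35.9 to 112) and Mbp 59.1-fold (34.9 to 99.9). Without cortex TRAP replicate 1 the log2 change of Camk2a went from 5.99 to 6.76, and without cortex TRAP replicate 2 that of Mbp from 5.88 to 6.50. Id3, a transcriptional regulator, fell by 4.74 on the log2 scale (SE 0.38), from 186 ± 8.87 to 6.95 ± 2.77 normalized CPM (SD, n = 3), Zfp36l1, which destabilises AU-rich messages, fell by 4.58 (SE 0.50), Hes5, a Notch target, by 5.02 (SE 0.67, and -6.03 with GC-corrected offsets), and Sox9, an astrocyte transcription factor, by 2.85 (SE 0.29). Slc1a2 (0.36 ± 0.24, 95% interval -0.15 to 0.87), Kcnj10 (-0.14 ± 0.29, -0.74 to 0.46), Sparc (-0.02 ± 0.27, -0.59 to 0.55) and Sparcl1 (-0.05 ± 0.23, -0.53 to 0.42) did not pass the test, and the last 3 changed sign under other settings.

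Astrocyte markers fell in 24 of 29 members (25 adjusted over the list alone, median -1.53, adjusted p = 6.78e-10, and adjusted p = 0.113 with an estimated correlation), and held 8.61%, 10.6% and 11.9% of the nuclear counts in cortex TRAP replicates 1, 2 and 3. PAP TRAP replicate 2 lay inside that range with 10.1%, against 5.20% and 6.73% in PAP TRAP replicates 1 and 3. Single markers were Gpr37l1, a receptor of astrocytes, at -2.87 ± 0.34, Glul at -1.26 ± 0.25, Slc1a3 at -1.08 ± 0.24, Aqp4 at -1.28 ± 0.33 and Gfap at -1.34 ± 0.29. Aldh1l1 fell by 1.53 (SE 0.42), with an adjusted p of 0.0548 without cortex TRAP replicate 3 and 0.0539 without PAP TRAP replicate 1. Dendritic and neuropil mRNAs rose in 15 of 17 (15 adjusted over the list alone, median 4.02, adjusted p = 1.27e-26), with Shank1 at 5.35 ± 0.34 (4.43 with GC-corrected offsets) and the calcium channel Itpr1 at 5.0 ± 0.28. Presynaptic genes rose in 15 of 18 (15 adjusted over the list alone, adjusted p = 4.14e-18), with Bsn at 5.38 ± 0.28 (4.65 with GC-corrected offsets), and neuron markers in 20 of 22 (20 adjusted over the list alone, adjusted p = 1.01e-18, and adjusted p = 0.05003 with an estimated correlation), with the chloride transporter Slc12a5 at 6.32 ± 0.43. Myelin markers rose in 12 of 16 (12 adjusted over the list alone, adjusted p = 6.2e-09). Microglia markers rose in 10 of 18 (12 adjusted over the list alone, adjusted p = 1.99e-05, and adjusted p = 0.147 with an estimated correlation), with Csf1r at 5.06 ± 0.41. All 11 mitochondrially encoded mRNAs rose (11 adjusted over the list alone, median 7.52, adjusted p = 7.99e-27), with mt-Co1 going from 44.2 ± 6.30 to 17919 ± 4205 normalized CPM.

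Respiratory chain genes encoded in the nucleus went the other way and fell in 37 of 59 (46 adjusted over the list alone, median -1.30, adjusted p = 2.43e-09, and adjusted p = 0.155 with an estimated correlation). Cytosolic ribosomal protein genes fell in 19 of 72 (11 adjusted over the list alone, adjusted p = 1.78e-05, and adjusted p = 0.203 with an estimated correlation). Genes for actin and membrane linkers of processes fell in 11 of 17 and rose in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00329, and adjusted p = 0.105 with an estimated correlation), with the actin-severing Cfl1 at -1.75 ± 0.27. Ezr, a linker of membrane and actin in fine astrocyte processes, was lower by an estimated -0.90 ± 0.30, a call that ended without any of cortex TRAP replicates 1, 2 and 3 or PAP TRAP replicate 1, or without mitochondrial genes (adjusted p from 0.0507 to 0.192). Water, potassium and gap junction channels fell in 6 of 11 and rose in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0164, and adjusted p = 0.263 with an estimated correlation). Astrocyte synaptic regulators had 2 higher and 6 lower of 18 (2 and 6 adjusted over the list alone, adjusted p = 0.231), and held 1.48% of the nuclear counts in PAP TRAP replicate 2, against 0.882% and 1.04% in replicates 1 and 3. In total 4526 genes were called, 2577 higher and 1949 lower, against a median over all genes of -0.28. The lower genes numbered 1179, 1264 and 1277 without cortex TRAP replicates 1, 2 and 3 and 1287 without PAP TRAP replicate 1, and with GC-corrected offsets 2373 were higher and 2374 lower. Of the 2610 genes lower in cortex TRAP than in cortex input, 1942 (74.4%) were among the 2577 higher in PAP TRAP. Of the 2127 genes higher in cortex TRAP than in cortex input, 33 (1.55%) were. Both comparisons share the cortex TRAP libraries, which may add to the first of these overlaps.

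**Figure D3:**
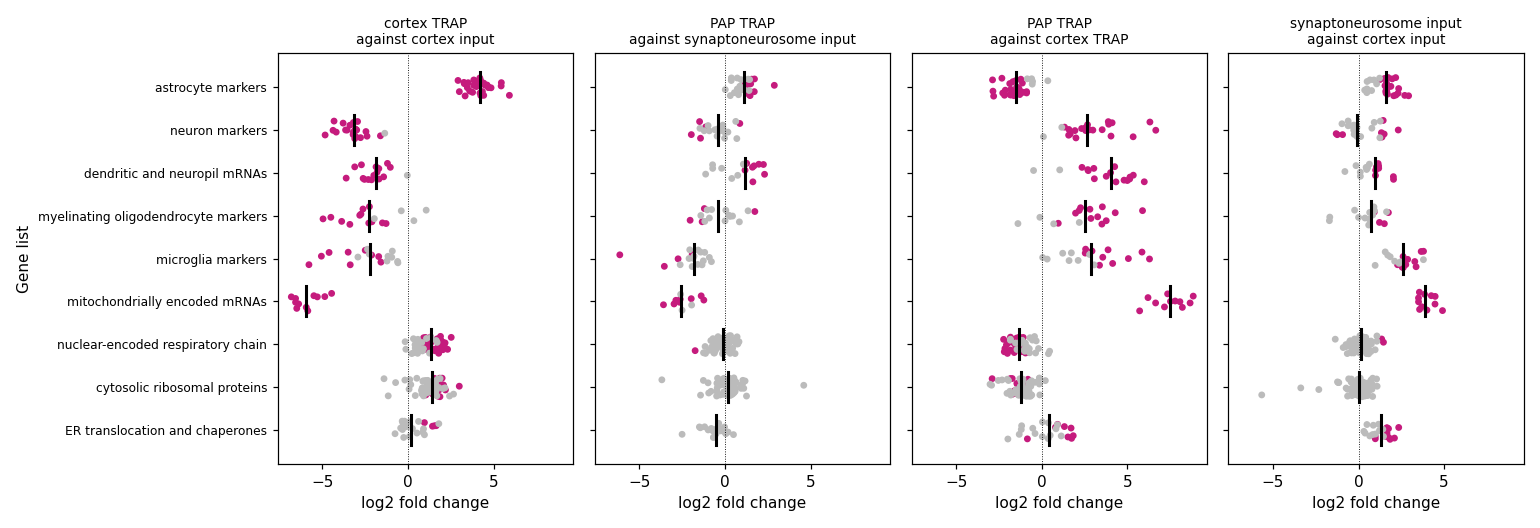
Log2 fold changes of the members of 9 gene lists in the 4 comparisons between groups, with magenta points for an adjusted p under 0.05, grey points for the others and a black line at the list median. Astrocyte markers had medians of 4.19 in cortex TRAP against its input, 1.09 in PAP TRAP against its input and -1.53 in PAP TRAP against cortex TRAP, while dendritic and neuropil mRNAs had -1.87, 1.16 and 4.02.

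The difference between both enrichments tests whether the change over input differed between the fractions. It did for astrocyte and neuronal genes in opposite directions. A higher value in the fraction can be a larger rise or a smaller fall over input. A lower value can come from a richer input as well as from a lower level in the immunoprecipitate. Glul was enriched less in the fraction by 2.95 on the log2 scale (difference -2.95 ± 0.36), Slc1a2 by a difference of -2.56 ± 0.35 and Sparc by -3.15 ± 0.40. Camk2a had a difference of 4.81 ± 0.47, Mbp of 4.38 ± 0.43 and Malat1 of 3.99 ± 0.63. Leaving out a library moved these to 5.6 for Camk2a (cortex TRAP replicate 1), 5.01 for Mbp (cortex TRAP replicate 2) and 4.90 for Malat1 (synaptoneurosome input replicate 3). Of 29 astrocyte markers, 27 had a lower enrichment in the fraction (28 adjusted over the list alone, adjusted p = 7.76e-34), and of 17 dendritic and neuropil mRNAs, 15 had a higher one (15 adjusted over the list alone, adjusted p = 2.29e-19). In total 2699 genes differed, 1721 with the higher and 978 with the lower value in the fraction. The 978 became 627 without cortex input replicate 3.

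Genes higher in PAP TRAP than in both its own input and cortex TRAP numbered 177, where independent lists would share 77.3. The set held Camk2a, Mbp, Dst, a linker of cytoskeletal filaments (1.89 ± 0.26 over input), Myh9, a non-muscle myosin (2.96 ± 0.51), and Arhgap33, a regulator of small GTPases (2.26 ± 0.34, and 1.62 with GC-corrected offsets). Of the 177, 95 were lower in cortex TRAP than in cortex input and 17 were higher. Those 17, singled out after their values were seen, include Myo6, a myosin motor (1.93 over input, 2.84 over cortex TRAP and 1.64 for cortex TRAP over its input), Amot, a scaffold of cell junctions (2.58, 2.96 and 2.19), and Ptprz1, a receptor phosphatase of glia (1.05, 1.497 and 2.27). At unadjusted p-values under 0.05 the overlap was 511 genes, against a mean of 37.9 and a highest value of 45 in 10 simulations of unchanged groups that share the PAP TRAP libraries. The simulated groups hold no differences, so they do not show what the shared libraries add where both comparisons hold real changes. Part of the excess of 177 over 77.3 may come from those shared libraries. The count was 99, 85 and 96 without synaptoneurosome input replicates 1, 2 and 3, 105 and 113 without PAP TRAP replicates 1 and 3, and 71 with GC-corrected offsets, 70 of them among the 177.

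Genes higher in cortex TRAP than its input and lower in PAP TRAP than in cortex TRAP numbered 1075, where independent lists would share 310. They are 50.5% of the 2127 genes that rose in cortex TRAP and include Id3, Hes5, Zfp36l1 and Cth, an enzyme of cysteine synthesis (-4.82 ± 0.83 in PAP TRAP against cortex TRAP, and -5.70 without PAP TRAP replicate 2). At unadjusted p-values the overlap was 1589, against a mean of 42.6 and a highest value of 51 in 10 simulations of unchanged groups. Here too the simulations cannot show what shared libraries add where groups differ. Part of the excess of 1075 over 310 may come from the cortex TRAP libraries, which both comparisons share. The count was 695 and 697 without cortex input replicates 1 and 3, 626, 685 and 690 without cortex TRAP replicates 1, 2 and 3, and 708 without PAP TRAP replicate 1. Of the 2127 genes, 198 (9.31%) rose and 6 fell in PAP TRAP against synaptoneurosome input.

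**Figure D4:**
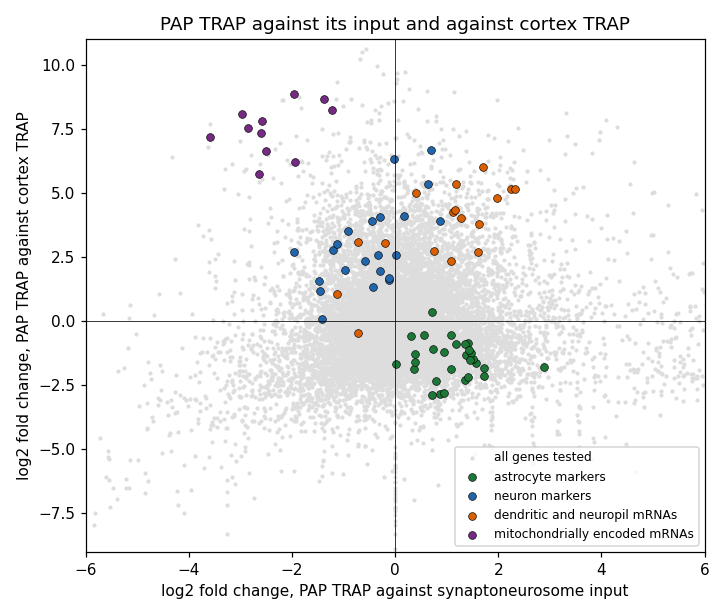
Log2 fold change of PAP TRAP against synaptoneurosome input (x) and against cortex TRAP (y) for each gene tested, with the members of 4 gene lists coloured; 109 genes lie outside the axes. Dendritic and neuropil mRNAs sit at medians of 1.16 and 4.02 and astrocyte markers at 1.09 and -1.53.

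Positions of the genes used most, in GENCODE M21 on GRCm38, are chromosome 2 from 102658659 to 102790784 for Slc1a2, chromosome 1 from 153899944 to 153909723 for Glul, chromosome 6 from 90486427 to 90600203 for Aldh1l1, chromosome 18 from 60925618 to 60988152 for Camk2a and chromosome 18 from 82475146 to 82585637 for Mbp, all protein-coding. Rpl10a, the tagged protein (chromosome 17 from 28328471 to 28331033), had means of 1.04 to 6.51 normalized CPM over the groups and was called in none of the comparisons, at a level made uncertain by its pseudogene copies. C1qa, a complement gene of microglia, was called in none of the 5 comparisons either.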

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

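The tests of uniform carry-over, of an untagged control, of the spread between libraries and of the immunoglobulin chains without Ighm were chosen only after the result was seen.

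The change over input differed between whole tissue and the synaptoneurosome fraction for 2699 genes, by the interaction term of the fit. Astrocyte groups had the lower value in the fraction. The median log2 difference was -3.13 for astrocyte markers, -3.13 for water, potassium and gap junction channels, -2.60 for astrocyte synaptic regulators, -2.24 for glutamate and GABA uptake and metabolism, -1.85 for cholesterol synthesis and -1.52 for fatty acid synthesis and desaturation. Neuronal groups had the higher value, with 3.12 for dendritic and neuropil mRNAs, 2.84 for neuron markers and 2.63 for presynaptic vesicle and release genes. A higher value is not by itself a rise over input. The median log2 ratio to the synaptoneurosome input was -0.33, -0.85 and -0.07 for neuron markers in PAP TRAP replicates 1, 2 and 3. For dendritic and neuropil mRNAs it was 1.45, 0.85 and 1.06. For 9 further lists the camera call was lost with an estimated correlation. These were mitochondrially encoded mRNAs (3.53, adjusted p = 0.0895 with an estimated correlation), nuclear long noncoding RNAs (3.99, adjusted p = 0.0551 with an estimated correlation), myelinating oligodendrocyte markers (1.78, adjusted p = 0.0539 with an estimated correlation), the nuclear-encoded respiratory chain (-1.44, adjusted p = 0.123 with an estimated correlation) and cytosolic ribosomal proteins (-1.27, adjusted p = 0.213 with an estimated correlation). The others were glycolysis, glycogen and lactate (-0.68, adjusted p = 0.338 with an estimated correlation), actin and membrane linkers (-0.86, adjusted p = 0.0861 with an estimated correlation), reactive astrocyte genes (-2.63, adjusted p = 0.0673 with an estimated correlation), and ER translocation and chaperones (-0.80, adjusted p = 0.0625 with an estimated correlation).

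Single genes differed in the same test. The log2 difference was -2.56 for Slc1a2, -3.39 for Slc1a3, -2.95 for Glul, -3.13 for Gja1, -3.46 for Aqp4, -3.12 for Gfap, -2.80 for Kcnj10, -3.17 for Ezr, -3.15 for Sparc and -2.94 for Sparcl1. For Aldh1l1 it was -2.02, and its adjusted p lay between 0.0541 and 0.104 without cortex input replicates 1 or 2, cortex TRAP replicates 1 or 3, synaptoneurosome input replicates 1 or 2, or PAP TRAP replicate 1. Slc1a2, Kcnj10, Sparc and Sparcl1 did not pass the test between both immunoprecipitates, but were higher in synaptoneurosome input than in cortex input. Their lower enrichment thus goes with a richer input. Neuronal and other genes had the higher value in the fraction, with 4.81 for Camk2a (5.6 without cortex TRAP replicate 1), 3.27 for Slc17a7, 3.18 for Gad1, 4.38 for Mbp (5.01 without cortex TRAP replicate 2), 3.99 for Malat1 (4.90 without synaptoneurosome input replicate 3) and 5.11 for mt-Co1. The value of mt-Co1 reflects a smaller fall, since this gene was below its input in both immunoprecipitates. Slc17a7, Gad1 and Malat1 were not called higher than their input in PAP TRAP either.

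The largest positive differences were 8.46 for the long noncoding RNA Miat (9.51 without cortex TRAP replicate 3 and 9.39 without synaptoneurosome input replicate 3), 7.08 for Klhl34 (8.01 without cortex TRAP replicate 1 and 6.49 with GC-corrected offsets), 6.05 for Camsap3 (4.51 without PAP TRAP replicate 3), 6.04 for Lcp1 (8.67 without cortex TRAP replicate 1) and 5.91 for Fzd5. Fzd5 went to 2.16 without PAP TRAP replicate 3 (adjusted p = 0.423) and lost its call without cortex input replicate 3 or synaptoneurosome input replicates 1 or 2 (adjusted p from 0.0518 to 0.0675). Syt2 (7.62), mt-Tp (7.62), Kit (6.13) and mt-Tm (5.90) were at or near 0 counts in cortex TRAP, so these values depend on the prior count. Without cortex TRAP replicate 1 Syt2 had 8.44 and mt-Tp 9.20, without cortex TRAP replicate 2 Kit had 7.33, and without synaptoneurosome input replicate 1 mt-Tm had 6.51.

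The largest negative differences were -6.64 for Dnm2, -6.24 for Ifitm3, -5.77 for Zfhx4, -5.62 for C1qtnf6, -5.12 for Atp13a4, -5.09 for Decr1, -5.01 for Leprot, -4.89 for Nudt2, -4.78 for Ttr and -4.75 for Eva1a. Without cortex TRAP replicate 1 the calls ended for Dnm2 (-1.0, adjusted p = 0.302), Zfhx4 (1.92, adjusted p = 0.136), C1qtnf6 (-3.51, adjusted p = 0.121), Atp13a4 (-1.19, adjusted p = 0.633), Leprot (-1.90, adjusted p = 0.160) and Nudt2 (-3.48, adjusted p = 0.0530). Zfhx4 lost its call without each of the 10 libraries other than cortex TRAP replicates 2 and 3 (adjusted p from 0.0639 to 0.136). C1qtnf6 also lost it without cortex input replicate 3, synaptoneurosome input replicates 1 or 3, or PAP TRAP replicates 1 or 3 (adjusted p from 0.0574 to 0.183), and Atp13a4 without cortex input replicates 1, 2 or 3, synaptoneurosome input replicates 2 or 3, or PAP TRAP replicates 1 or 3 (adjusted p from 0.0507 to 0.302). Ifitm3 had -7.20 and Decr1 -6.27 without PAP TRAP replicate 2. Without synaptoneurosome input replicate 2 Ifitm3 had -5.44 and Nudt2 -4.03, and without replicate 1 of that group Ttr had -4.02, Eva1a -3.96 and Dnm2 -6.05. Decr1 had -4.41 without cortex TRAP replicate 1.

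Reads outside the gene counts also differed, with 30.9% ± 1.45 (SD, n = 3) not uniquely aligned in cortex TRAP against 18.04% ± 0.535 in cortex input, 24.8% ± 4.10 in PAP TRAP and 17.5% ± 1.78 in synaptoneurosome input.

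Dendritic and neuropil mRNAs stood above their own input in PAP TRAP. Uniform carry-over of synaptoneurosome RNA alone would move this list and the neuron markers alike, but their medians differed by 1.54 ± 0.35 (SD, n = 3) on the log2 scale (1.78, 1.70 and 1.14 in PAP TRAP replicates 1, 2 and 3), which argues against it as the whole cause. The list is rich in GC (median 58.6% against 49.4% of all genes tested), and with GC-corrected offsets 6 of its 9 called members stayed called while its median went from 1.16 to 0.75 and the value of Shank1, picked after its values were seen, from 1.18 to 0.50. Camk2a went from 1.70 ± 0.32 to 1.49 ± 0.32 (adjusted p = 0.0200), so GC content is not the whole of the pattern but may be part of it. Selective carry-over of neuronal ribosomes or RNA particles stays open, since 0 libraries of an immunoprecipitation without the tag were analysed here, and uptake or expression of these messages in astrocyte processes was not tested.

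PAP TRAP against its input called 605 genes, while cortex TRAP against its input called 4737, a ratio of 7.83. With nuclear counts of all libraries thinned to 1423296, the lowest ratio in 5 thinnings was 6.24 (4695 against 724 genes at full depth, also without mitochondrial genes), which argues against depth as the cause. The median rise of astrocyte markers was 4.16 in whole tissue and 1.08 in the fraction, a difference of 3.08 with median SEs of 0.29 and 0.36, each fitted on its own libraries, so a larger spread does not account for it. A candidate explanation is that the fraction's input is already rich in astrocyte RNA, as astrocyte markers rose in it by a median of 1.60. This is less than the 3.08 gap, and the rest goes with lower astrocyte markers in PAP TRAP than in cortex TRAP. Whether less tagged RNA in the immunoprecipitate lies behind those lower levels stays open. Lower calls also dropped, from 2610 in cortex TRAP to 204 in PAP TRAP, each over its input, and higher calls from 2127 to 401. Of the 2610 genes, 144 (5.52%) were lower and 95 higher in PAP TRAP than in its input, with a median log2 change of -0.20. The values for astrocyte markers do not address these genes.

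Irf4 and Pou2af1, transcription factors of B lineage cells, had more counts in several immunoprecipitated libraries than in the inputs, with the most in replicate 2 of PAP TRAP (578 and 788) and of cortex TRAP (368 and 244). These 2 libraries also had the most Ighg1 counts (145 and 171) and reads not aligned (11.9% and 11.3%, against 4.6% to 6.22% in the other 4 immunoprecipitated libraries). The test set in advance, over 18 other genes of antibody-secreting cells, found no rise in the 6 immunoprecipitated libraries (ratio of means 0.646, exact permutation p = 0.208, two-sided, smaller input ratio 1.32), but Ighm and Pim2 held 86.8% of the list's input counts, so this sum speaks neither against carried-in RNA nor for B lineage cells of the tissue. Of the 3 groupings run, those picked after the counts were seen gave exact permutation p = 0.00216, the smallest that 924 assignments allow, for 7 genes, 6 immunoglobulin chains other than Ighm and Jchain (59 input counts against 949) and for Igkc, Ighg1, Ighg2b and Jchain (5 against 922). The larger input ratio of the 7 genes was 0.138, so carried-in RNA may be a source for them, but genes picked this way settle nothing, Ighg2c went the other way, and both explanations stay open.

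Other splits of the libraries were counted for each number of genes called. For each comparison between groups, 1 of 10 splits, the real one, gave a count as large and the highest other count was 0, against 4737 for cortex TRAP over input, 605 for PAP TRAP over input, 4526 for PAP TRAP over cortex TRAP and 1246 for the inputs. With 10 splits no share under 0.05 can be reached. For the difference between enrichments, 1 of 100 splits reached 2699 (highest other 267), and for the genes higher in cortex TRAP and lower in PAP TRAP 1 of 100 reached 1075 (highest other 705). These splits mix libraries of groups that differ strongly, so for both counts they exclude only an arbitrary labelling of the libraries. They do not test either count apart from the differences between groups. For the genes higher in PAP TRAP than in both its input and cortex TRAP, 5 of 100 splits gave 177 or more, so the splits do not exclude chance. The other 4 gave 1176 to 1209 and all put the 3 cortex TRAP libraries in the place of PAP TRAP, which points to a structure of the samples: they hold a real difference between groups and measure more than chance. In 10 simulations of unchanged groups edgeR gave an overlap of at most 0 genes (45 at an unadjusted p under 0.05, against 511 observed). Such simulations hold no differences between groups, so they do not bound the overlap where groups differ.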

How the results depend on the processing

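The fits without mitochondrial genes, with thinned nuclear counts and with GC- or length-corrected offsets, and the list tests without 1 library, were chosen only after the data had been seen. Of the values for named genes under other settings, 2285 kept direction and side of the threshold, 36 lost the call, 16 gained one and 7 changed sign. With a library left out the numbers were 2574, 261, 9 and 24. The cause was not tested for any change below, except that leaving out a library leaves fewer samples and a minimum fold is stricter by construction.

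For PAP TRAP against synaptoneurosome input the count of 605 became 1253 with DESeq2, 137 with a minimum fold of 1.5, 329 with GC-corrected offsets and 292 to 521 with a library left out. Its share of higher calls was 66.3%, against 79.1% without mitochondrial genes, 54.7% with DESeq2 and 56.2% with GC-corrected offsets. For synaptoneurosome input against cortex input, 1246 became 2035 with DESeq2, 2251 with these groups alone, 547 with a minimum fold and 608 to 1025 with a library left out. The 177 genes higher in PAP TRAP than in both other groups became 266 with DESeq2, 52 with a minimum fold, 71 with GC-corrected offsets and 85 to 216 with a library left out. With length-corrected offsets the set held 122 genes, 119 of them among the 177. The 1075 genes higher in cortex TRAP and lower in PAP TRAP became 686 with a minimum fold and 626 to 1128 with a library left out. With length-corrected offsets this set held 1072 genes, 646 of them among the 1075. PAP TRAP against cortex TRAP then called 3890 genes, 3015 of them among the 4526 of the main fit. Of 120 list tests, 73 were called, against 38 with an estimated correlation. With a library left out, total counts stayed within 1.5 times for cortex TRAP over input (3859 to 4399), PAP TRAP over cortex TRAP (3566 to 4561) and the difference (2161 to 2999), but not each direction. The 1949 lower genes of PAP TRAP over cortex TRAP became 1179 without cortex TRAP replicate 1, and the 978 of the difference 627 without cortex input replicate 3.

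Changes of sign concerned small or unstable values. Gad1 in PAP TRAP over its input (0.01) was -0.0379 with RLE, -0.0387 with DESeq2, -0.0032 with the replicate block and -0.22 to 0.13 with a library left out. In PAP TRAP against cortex TRAP, Sparc (-0.02) was 0.0193 with RLE, 0.0193 with DESeq2, 0.105 without mitochondrial genes and -0.47 to 0.23 with a library left out, and Sparcl1 (-0.05) was 0.0775 without mitochondrial genes and -0.25 to 0.21 with a library left out. With a library left out, Gja1 ranged from -0.13 to 0.63 and Aqp4 from -0.17 to 0.65 in PAP TRAP over its input, and Kcnj10 from -0.53 to 0.10, Snap25 from -0.0145 to 0.36 and Malat1 from -0.69 to 0.10 in PAP TRAP against cortex TRAP. In the difference, Zfhx4 ranged from -6.19 to 1.92, Rpl10a from -1.29 to 0.24 and C1qa from -0.31 to 4.6. Leaving out mitochondrial genes moved the median of all genes from 0.06 to 0.17 in PAP TRAP over its input, from -0.28 to -0.11 in PAP TRAP against cortex TRAP and from 0.03 to 0.14 in the difference.

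Not every pair of libraries with the same replicate number had correlated deviations, so the libraries were treated as unpaired. Over the 18 pairs with the same number, deviations from group means correlated by -0.048 to 0.135, with 4 pairs over 0.1, against -0.163 to 0.081 for other pairs, and 7 of 12 libraries correlated best with their own number in every group, a hint of pairing from the data and not from the design. With the replicate number as a block the counts were 4770, 653, 4564, 1358 and 2726 for cortex TRAP over input, PAP TRAP over input, PAP TRAP over cortex TRAP, the inputs and the difference, 191 and 1123 for the paired sets, and 77 list tests. Of the values for named genes, 390 kept direction and side of the threshold with this block, 6 lost the call, 2 gained one and 1 changed sign. With nuclear counts thinned to 1423296 per library, PAP TRAP over its input called 669 to 706 genes in 5 thinnings, against 605 at full depth and 724 at full depth without mitochondrial genes, which the thinned fits also leave out. What depth limits for genes of low level was not tested.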

Other observations

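The values of Scd1 and Fasn in PAP TRAP against cortex TRAP were picked after they were seen, the other genes were named by the preset rule, and of the tests here only those of lists without 1 library were chosen after the result was seen.

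Lipid synthesis genes were prominent in cortex TRAP. Of 21 genes of fatty acid synthesis and desaturation, 14 rose and 3 fell over input (14 and 3 adjusted over the list alone, adjusted p = 1.17e-08), with the desaturase Scd1 at 4.39 ± 0.28 and Acsbg1, an acyl-CoA synthetase, at 5.92 ± 0.39. In the synaptoneurosome input 10 rose over cortex input (14 adjusted over the list alone, adjusted p = 5.45e-12). In PAP TRAP over its input 7 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0208, adjusted p = 0.162 with an estimated correlation and adjusted p = 0.0603 without PAP TRAP replicate 2), and against cortex TRAP 6 fell (6 adjusted over the list alone, adjusted p = 0.32), with Acsbg1 at -2.18 ± 0.33 and Acly, which makes acetyl-CoA, at -2.29 ± 0.50. Without cortex TRAP replicate 1 Acly had -1.04 (adjusted p = 0.0678). These genes held 1.098% of the nuclear counts in PAP TRAP replicate 2, against 0.678% and 0.853% in replicates 1 and 3 and 1.08% to 1.33% in cortex TRAP. Scd1 had 0.06 ± 0.24 and Fasn -0.06 ± 0.25, and neither passed the test. Cholesterol synthesis rose in 14 of 21 in cortex TRAP (15 adjusted over the list alone, adjusted p = 1.65e-06), and in PAP TRAP against cortex TRAP 11 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.00262, and adjusted p = 0.0795 with an estimated correlation), with Msmo1, a demethylase of late cholesterol synthesis, at -2.08 ± 0.29. Genes of glycolysis, glycogen and lactate rose in 8 of 19 in cortex TRAP and fell in 1 (9 and 2 adjusted over the list alone, adjusted p = 0.000609, and adjusted p = 0.219 with an estimated correlation). Against cortex TRAP, 7 were lower and 1 higher in PAP TRAP (7 and 1 adjusted over the list alone, adjusted p = 0.0109, adjusted p = 0.348 with an estimated correlation and adjusted p = 0.058 without cortex TRAP replicate 1), with Eno1, a glycolytic enzyme, at -1.90 ± 0.32.

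The ER chaperones Hspa5 (1.74 ± 0.28) and Hsp90b1 (1.84 ± 0.31) were higher in PAP TRAP than in cortex TRAP, but their list was not called, with 7 of 22 ER genes higher and 1 lower (8 and 2 adjusted over the list alone, adjusted p = 0.317). Against its own input 0 of the 22 were called by the edgeR quasi-likelihood test (0 adjusted over the list alone, list adjusted p = 0.00216, median -0.50). Reactive astrocyte genes rose in 4 of 7 in the synaptoneurosome input (4 adjusted over the list alone, adjusted p = 0.000198), with Vim, an intermediate filament, at 2.42 ± 0.55 and an adjusted p of 0.0512 without cortex input replicate 3. Oligodendrocyte precursor markers fell in 6 of 9 in cortex TRAP and rose in 1 (6 and 3 adjusted over the list alone, adjusted p = 0.299), the one that rose being Olig1 (1.43 ± 0.30), a transcription factor. Immediate early genes, induced by neuronal activity, had 1 higher and 2 lower of 13 in cortex TRAP (0 and 1 adjusted over the list alone, adjusted p = 0.317), with Egr1 at -2.30 ± 0.47. Endothelial markers were higher in 4 of 7 in PAP TRAP than in cortex TRAP (5 adjusted over the list alone, adjusted p = 0.150), pericyte and smooth muscle markers in 2 of 5 with 1 lower (2 and 1 adjusted over the list alone, adjusted p = 0.801), and ependymal and choroid plexus markers were lower in 2 of 5 (2 adjusted over the list alone, adjusted p = 0.131), with Ttr at -3.71 ± 0.58. Red blood cell genes, with 4 tested, were too few for a list test, and 1 fell in cortex TRAP (1 adjusted over the list alone), Hbb-bs, a globin, at -3.19 ± 0.99, with an adjusted p of 0.0647 without cortex input replicate 1.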
